A study of Homo sapiens with 6 samples.

How the data were processed

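Total RNA was measured by sequencing in 6 libraries of HEY cells, an established human ovarian cancer line, 3 with a control siRNA (siNC) and 3 with a CCNL2-targeting siRNA (siCCNL2), grouped by the genotype given in the labels. The deposited count table holds whole-number read counts per gene, not normalized, with a different total in each library. The submitters' processing notes name fastp 0.23.0, HISAT2, HTSeq 2.0.1 and the genome build GRCh38, with no role or order. The annotation release, the library kit and whether strand was used in counting were not given in the sources used here, so reads of a gene and of an overlapping or antisense partner cannot be told apart. The sequences of both siRNAs were likewise not given in the sources used here.

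The table has 62710 rows for 60835 distinct gene names, because some names were joined to several Ensembl identifiers and then repeat the same values, the name Y_RNA alone in 758 rows. Each name was used once. A second deposited table holds a TPM-like score made by the authors from gene length and library size. Its columns sum to 1000000 over distinct names and to more over all rows, which is why the column as deposited is treated as a score. Dividing count by score gave 1 factor per gene and library within a relative deviation of 1.32e-09 over 9661 genes, so both tables hold the same measurement. No column belonged to another sample.

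Total counts over distinct names ran from 13596286 to 18095529 per library. Genes were kept by filterByExpr with the groups as given, which left 15346 genes and more than 99% of the counts in each library. Tests used edgeR 4.0.16 in R 4.3.3, with TMM factors, estimateDisp and the quasi-likelihood test (glmQLFit, glmQLFTest) without covariates, and Benjamini-Hochberg adjustment over the 15346 genes. A gene was called at an adjusted p under 0.05. Fold changes are siCCNL2 over siNC, the standard error of a log2 fold change is its size over the square root of F, and CPM values are TMM-scaled. A single value was also compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. On counts simulated from these libraries, with 50 genes changed at each size among 15095 tested, the test recovered 46% at 1.25-fold, 66% at 1.5-fold, 72% at 2-fold and 94% at 3-fold, with 10 false calls. Far fewer genes changed there than were called in these data, which makes the adjusted threshold stricter, so these rates are not the power of this comparison. Counting precision is highest for deeply counted genes, and intervals and standard errors cover only these libraries.

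Before the data were examined, 32 gene lists were fixed. Of these, 31 had at least 5 tested members and were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with a correlation estimated for each list, and fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes, were run beside it. In 30 null lists simulated on these libraries camera made 0 calls, and it called a list of 30 genes shifted by 0.3 on the log2 scale. Genes were drawn independently of each other there, so this does not test the preset correlation on lists whose genes vary together. Among the lists called here, estimated correlations ran from 0.0107 (type I interferon response) to 0.179 (heat shock response).

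Named genes followed a rule also fixed before the data were examined. It takes CCNL2, CCNL1, CDK11A and CDK11B, then 8 ferroptosis genes whatever their result. It adds the 12 largest changes per direction and the 5 smallest p-values per direction, among called genes with a mean of at least 5 CPM in the higher group, no overlap between the groups and a symbol that is not a bare or clone identifier. For each list described it takes up to 2 called members per direction. Some of these genes and 1 of the tested lists are not described here.

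Alternatives comprised DESeq2 1.42.0 size factors, upper-quartile factors and no composition factor, no count filter, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, limma-trend on log2 of the score plus 1 or plus 0.1, a stricter threshold of 0.01, a test against a fold of 1.2, a fold of at least 1.5, a fit with the replicate number as a block, and leaving out each library. Leaving out genes with a scan motif, meaning TCGGAGA, CGGAGAA, TGGAGAA, TCTGAGA or CTGAGAT in the 3' UTR, 7-mers that stood out in the scan of these data, removal of a trend over GC content and length, and KEGG pathways as annotated in the deposited table were added after the data had been seen. The first of these also left out tested genes for which no 3' UTR sequence was found.

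Coordinates are those of the deposited table on GRCh38. GENCODE release 29 on the same build was found by Ensembl identifier for 97.5% of tested genes, of which 99.9% lay on the same chromosome and 96.5% had both ends within 10000 bases. Sequences of 3' UTRs came from GENCODE release 29, taking for each gene the coding transcript with the longest annotated 3' UTR, which gave a sequence for 12295 of the 15346 tested genes. In the motif scan, genes had a mean of at least 5 CPM and a 3' UTR of at least 50 bases, fold changes were corrected for 3' UTR length and GC content, and each 7-mer present in at least 60 genes was scored by the mean rank of its genes. Permutation tests of a motif used 100000 resamples. Scans and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.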

Results

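RNA of HEY cells, an established human ovarian cancer line, was sequenced from 3 libraries with a CCNL2-targeting siRNA (siCCNL2) and 3 with a control siRNA (siNC). The protocol gives 48 h with the CCNL2 siRNA in the same words for all 6 libraries, so the groups were taken from the genotype label and the time of the controls is assumed to be equal. The series title places the experiment in a study of 5-methylcytosine, cisplatin resistance and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. Total counts were 16934044, 15771604 and 16011425 in siNC and 18095529, 13596286 and 15817416 in siCCNL2. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries of 1 group correlated at r = 0.991 to 0.992 in log2 CPM and libraries of different groups at 0.983 to 0.986. The first principal component of the 1000 most variable genes carried 47.3% of the variance and separated the groups, and the second carried 15.7%. Counts of libraries within a group differed by 2.19 to 3.65 times sampling noise. Each was counted as a separate sample, which this ratio does not test. Mitochondrial transcripts made up 3.22% to 3.39% of counts in siNC and 3.43% to 3.77% in siCCNL2.

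The first comparison asked how far the siRNA lowered its target. CCNL2, which encodes cyclin L2, a partner of the CDK11 kinases with roles in transcription and splicing, fell by 26.3% (258 ± 10.8 CPM in siNC to 190 ± 11.2 CPM in siCCNL2, mean ± SD, n = 3 each). The log2 fold change was -0.44 (SE 0.044, adjusted p = 2.15e-08 by edgeR's quasi-likelihood test). All 3 siCCNL2 libraries lay below all 3 siNC libraries, and the exact two-sided permutation p was 0.1, the smallest this design allows. The fall was 26.9% on the authors' deposited TPM-like score. CCNL2 (ENSG00000221978) lies on the minus strand of chromosome 1 at 1385711 to 1399335 of GRCh38. It ranked 433 by p, and 845 genes were called lower by more. Its paralogue CCNL1 (chromosome 3, 157146508 to 157160760) fell from 188 ± 9.83 to 166 ± 7.12 CPM (log2 fold change -0.18, SE 0.045, adjusted p = 0.0028). CDK11B, a kinase partner, stood at 56.1 ± 2.0 and 60.3 ± 2.58 CPM (log2 fold change 0.10, adjusted p = 0.168). CDK11A, a near-identical copy of CDK11B, averaged 10 counts per siNC library and 5.67 per siCCNL2 library and was too low to test, and counts of both are uncertain because reads can be shared between them.

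**Figure D1:**
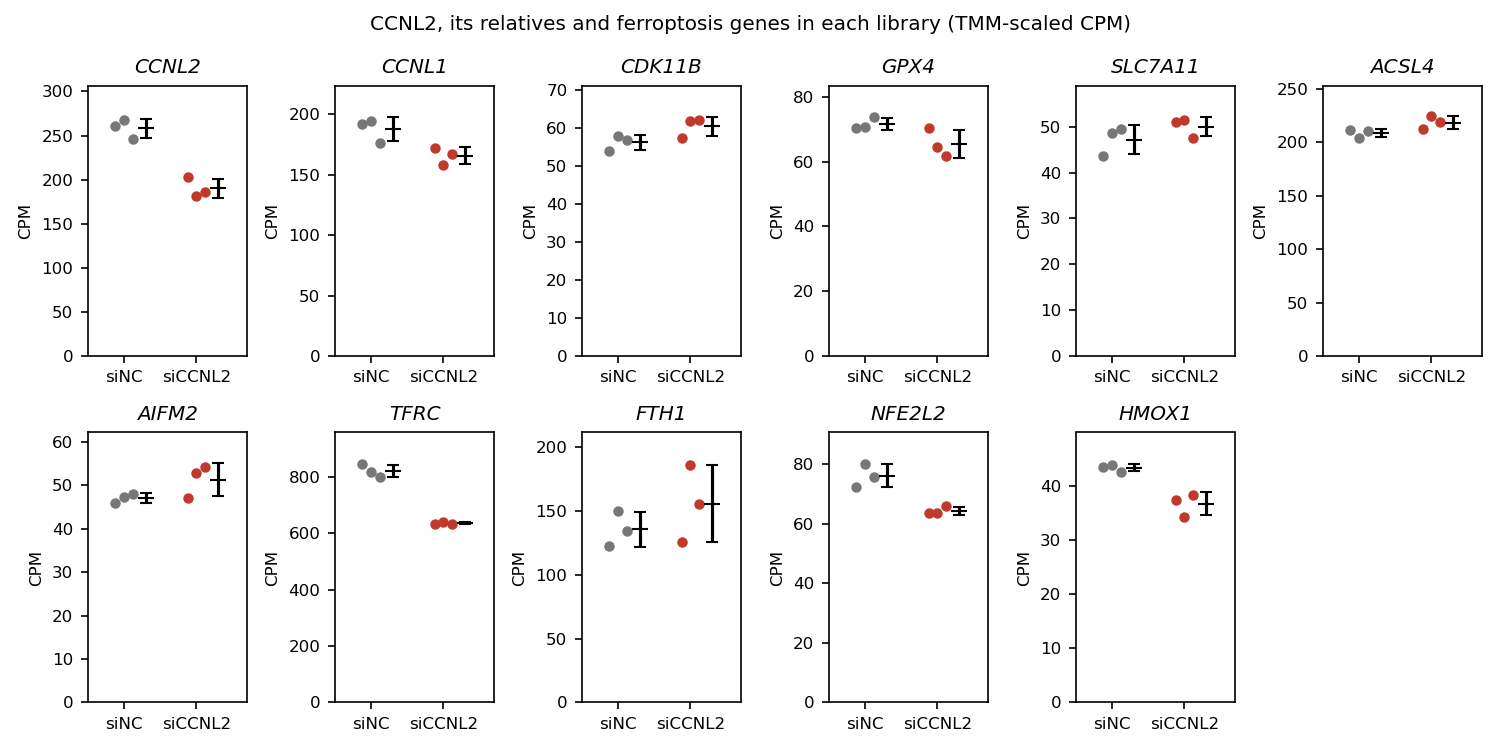
TMM-scaled CPM (y axis, from 0) of CCNL2, its relatives and 8 ferroptosis genes in each library of siNC (grey) and siCCNL2 (red), with the mean ± SD of 3 libraries as a black bar. CCNL2 averaged 258 CPM in siNC and 190 CPM in siCCNL2, TFRC was lower in all 3 siCCNL2 libraries, and the groups overlapped for CDK11B, SLC7A11, AIFM2 and FTH1.

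Ferroptosis genes were compared because the series title names this process. TFRC, the transferrin receptor that brings iron into cells, fell from 820 ± 22.2 to 635 ± 3.55 CPM (log2 fold change -0.37, SE 0.032, adjusted p = 1.95e-09). NFE2L2, which encodes the antioxidant transcription factor NRF2, fell by 0.24 on the log2 scale (adjusted p = 8.06e-04), and HMOX1, a heme-degrading enzyme and NRF2 target, fell by 0.24 (adjusted p = 0.0044). GPX4, the glutathione peroxidase that removes lipid peroxides, stood at 71.7 ± 1.83 and 65.5 ± 4.4 CPM (log2 fold change -0.13, SE 0.055, adjusted p = 0.079). Its 3 siCCNL2 libraries lay below the 3 siNC libraries in CPM, narrowly for siCCNL2 replicate 1 (70.3 against 70.5 in siNC replicate 1). On the TPM-like score the groups overlapped, with siCCNL2 replicate 1 at 185.2 and siNC replicates 1 and 2 at 184.2 and 184.6. The cystine transporter gene SLC7A11 had a log2 fold change of 0.09 (adjusted p = 0.316), ACSL4, which loads polyunsaturated fatty acids into lipids, 0.07 (0.203), AIFM2, which encodes FSP1, 0.12 (0.132), and FTH1, ferritin heavy chain, 0.19 (0.09). GPX4, AIFM2 and FTH1 passed the threshold without siCCNL2 replicate 1 (adjusted p 0.0202, 0.0265 and 1.87e-04, log2 fold changes -0.18, 0.19 and 0.33). GPX4 also passed with upper-quartile factors (adjusted p = 0.0479), and FTH1 also passed without a count filter (4.29e-04) or with the replicate number as a block (0.0031). Over all 15 alternatives the log2 fold change ran from -0.18 to -0.08 for GPX4 (largest adjusted p 0.346), from 0.08 to 0.19 for AIFM2 (0.418) and from 0.05 to 0.33 for FTH1 (0.642). The lowest FTH1 value came without siCCNL2 replicate 2, and those of GPX4 and AIFM2 nearest to 0 came without siCCNL2 replicate 3. AIFM2 overlaps MACROH2A2 on the opposite strand over 14060 bases, a gene itself called higher, and its counts are uncertain for that reason. FTH1 has processed pseudogenes that can share its reads. NFE2L2 overlaps AC019080.1 on the same strand and HNRNPA3 on the opposite strand, neither of them called, and the lower AGPS over 11 bases.

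Across the ferroptosis defence list of 26 tested genes, 3 rose, 11 fell and 12 were not called, and 7 rose and 14 fell when adjusted over the list alone. The list was called lower by camera (median log2 fold change -0.13, adjusted p = 0.0314), but not with an estimated correlation (adjusted p = 0.57 with an estimated correlation). The largest falls were SLC40A1, the iron exporter ferroportin (log2 fold change -1.06, from 2.79 to 1.36 CPM), and TXNRD1, thioredoxin reductase (-0.51, 1542 ± 33.4 to 1080 ± 27.6 CPM). The largest rises were COQ2, of coenzyme Q synthesis (0.49), and SLC3A2, the partner chain of SLC7A11 (0.32). The call was lost without siNC replicate 3 (adjusted p = 0.0546), without siCCNL2 replicate 1 (0.0699) and on log2 of the score plus 1 (0.0507). It was also lost among genes without a scan motif (0.113) and after removal of the GC and length trend (0.0862), where the mean of -0.12 (SE 0.060, 26 members) was -0.12 (SE 0.077, 18 members) and -0.12 (SE 0.061). Of 28 ferroptosis execution genes, 4 rose, among them TMEM164 (0.46), and 5 fell, among them TFRC and STEAP3 (-0.31). The list was not called (adjusted p = 0.636). Adjusted over the list alone the counts were also 4 and 5. Of 9 transcripts used as markers of ferroptosis, 3 rose, led by TRIB3 (0.89) and ATF3 (0.54), and 2 fell, TFRC and HMOX1, with the same counts adjusted over the list alone and no call (adjusted p = 0.636). ATF3 was lost without siNC replicate 1 (adjusted p = 0.108) and without siCCNL2 replicate 2 (0.0904). Of 24 iron handling genes, 2 rose and 9 fell, both over all genes and adjusted over the list alone, with SLC39A14 at 0.45 and SLC40A1 and TFRC lowest, and the list was not called (adjusted p = 0.168). It was called lower without a count filter (adjusted p = 0.0061) and by fry (0.0129). The other riser, NFS1 (0.27), whose groups overlapped, lost its call under 9 alternatives, among them limma-voom (adjusted p = 0.0603), the DESeq2 Wald test (0.0892) and the omission of siNC replicate 1 (0.164), siNC replicate 2 (0.17), siCCNL2 replicate 2 (0.267) or siCCNL2 replicate 3 (0.059).

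Transcriptome-wide, 5159 of 15346 tested genes (33.6%) were called between siCCNL2 and siNC, 2634 higher and 2525 lower, a balance that turned with the scaling (2368 and 2783 with upper-quartile factors, 2536 and 2571 without a composition factor). Most differences were small: the median absolute log2 fold change of called genes was 0.33, and 359 changed at least 2-fold (149 higher, 210 lower). The groups did not overlap for 43.9% of genes, where chance gives 10%. The smallest p among higher genes belonged to GANAB, the catalytic subunit of the glucosidase that trims glycans in the endoplasmic reticulum (chromosome 11, 62624826 to 62646726). It rose from 267 ± 2.01 to 778 ± 11.5 CPM (log2 fold change 1.54, SE 0.033, adjusted p = 2.41e-20). CCDC80, a secreted matrix protein gene (chromosome 3, 112596797 to 112649530), rose from 288 ± 5.73 to 855 ± 28.9 CPM (1.57, SE 0.035, adjusted p = 3.09e-20). These were followed by the tropomyosin gene TPM4 (log2 fold change 1.53), the lysine methyltransferase gene SETD7 (1.79) and the nucleolar protein gene NOLC1 (1.23). Among genes averaging at least 5 CPM in the higher group, the largest rises were in the histone gene H2BC5 (2.13, 1.79 ± 0.216 to 7.87 ± 0.401 CPM), NLRP10 (2.04), the kinase gene CDK14 (1.81) and the potassium channel gene KCNJ2 (1.79). IGFBP3, which binds insulin-like growth factors (1.53), the collagen gene COL6A3 (1.52), OGFR (1.48) and the netrin gene NTN4 (1.40) completed the 12 largest. H2BC5 belongs to a multigene family, and CDK14 overlaps CLDN12 on the same strand over 46979 bases, so both are uncertain.

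Among lower genes, CCND1, which encodes cyclin D1 and drives entry into the cell cycle (chromosome 11, 69641156 to 69654474), had the smallest p and fell from 1760 ± 28.3 to 835 ± 6.32 CPM (log2 fold change -1.08, SE 0.030, adjusted p = 1.43e-18). It was followed by CACUL1 (log2 fold change -1.30), the laminin gene LAMA5 (-1.21), the tetraspanin gene CD82 (-1.41) and LTBP2, a binding protein of the extracellular matrix (-1.07). Under the same level limit, the largest falls were in the protease gene CTSW (-2.88, 5.53 ± 0.302 to 0.77 ± 0.307 CPM), the growth factor gene PDGFB (-1.91), PLSCR4 (-1.90) and the gelatinase genes MMP9 (-1.85, 17.7 ± 1.58 to 4.93 ± 0.471 CPM) and MMP2 (-1.84). RBFOX3 (-1.81), the tight junction gene CLDN4 (-1.75), AFAP1L2 (-1.69), HSD11B1, which regenerates cortisol (-1.61), the metalloprotease gene ADAM8 (-1.61), NANOS1 (-1.55) and SLC12A8 (-1.53) made up the rest. HSD11B1 and its antisense gene HSD11B1-AS1 overlap over 37948 bases and both were called lower, so they cannot be separated here. NANOS1 overlaps the far more abundant EIF3A (751 CPM) over 61 bases on the opposite strand. The 30 genes of the previous and present paragraphs were called in the same direction under all 15 alternatives run on single genes.

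**Figure D2:**
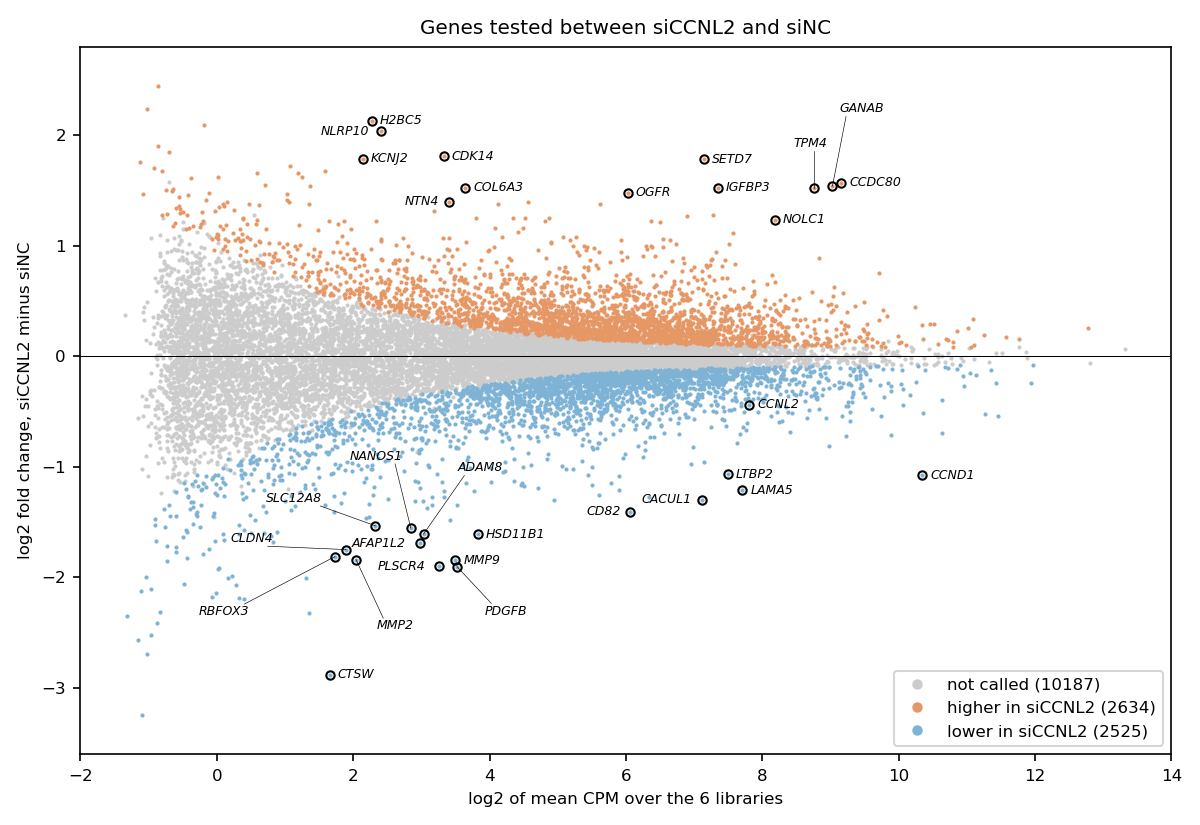
Each point is 1 of 15346 tested genes, with the log2 of its mean CPM over the 6 libraries on the x axis and the log2 fold change of siCCNL2 minus siNC on the y axis, coloured where called at an adjusted p under 0.05. GANAB, CCDC80, TPM4 and SETD7 stand above the cloud at high counts and CCND1 below it, while CCNL2 lies within it at -0.44.

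Of the 31 tested lists, 10 were called by camera, 5 higher and 5 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.353 and 4 lists had an unadjusted p under 0.05. Fry called 13 lists. The ATF4 integrated stress response list, targets of a transcription factor induced by amino acid shortage and other stresses, had the highest median (log2 fold change 0.37, adjusted p = 1.84e-09; adjusted p = 0.353 with an estimated correlation). Of its 30 tested genes 21 rose, 1 fell and 8 were not called, and 22 rose and 1 fell adjusted over the list alone. DDIT3, which encodes CHOP, rose by 1.18 on the log2 scale (1.4 ± 0.271 to 3.21 ± 0.528 CPM) and the glycine transporter gene SLC6A9 by 0.95, while STC2 fell by 0.17, a call lost without siCCNL2 replicate 1 (adjusted p = 0.074). Endoplasmic reticulum chaperones of the unfolded protein response rose in 13 and fell in 2 of 21 genes, 14 and 2 adjusted over the list alone (median 0.18, adjusted p = 9.47e-04; adjusted p = 0.353 with an estimated correlation). CRELD2 (0.51) and SDF2L1 (0.47) rose, and SYVN1 (-0.34) and DNAJB9 (-0.44) fell, DNAJB9 losing its call without siNC replicate 1 (adjusted p = 0.092) or siCCNL2 replicate 2 (0.0536). Heat shock genes rose in 8 and fell in 1 of 19, or 9 and 1 adjusted over the list alone (median 0.11, adjusted p = 0.0038; adjusted p = 0.447 with an estimated correlation), with HSPA1A, nearly identical to HSPA1B and so uncertain (0.45), FKBP4 (0.34) and, lower, the collagen chaperone gene SERPINH1 (-0.34). The heat shock call was lost among genes without a scan motif (adjusted p = 0.0579), with 13 members and a mean of 0.12 (SE 0.060) against 0.13 (SE 0.044) in all 19.

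Cell cycle lists were higher while CCND1 was lower. DNA replication genes rose in 19 and fell in 2 of 38, or 21 and 2 adjusted over the list alone (median 0.15, adjusted p = 1.93e-04; adjusted p = 0.353 with an estimated correlation), led by TYMS, thymidylate synthase (0.55), and PRIM1, a primase subunit (0.41). TYMS stood at 29.2 CPM in siCCNL2 replicate 2 against 18.2 and 21.9 in replicates 1 and 3. Its log2 fold change ran from 0.36 to 0.70 over the alternatives. GINS1 (-0.17) and RFC3 (-0.14) fell in the full set, but GINS1 was lost without siNC replicate 2 or 3 or without siCCNL2 replicate 1 or 3 and by the DESeq2 Wald test (adjusted p 0.0672 to 0.174) and RFC3 without siNC replicate 1 or 3 or siCCNL2 replicate 1 (0.0761 to 0.114). Mitosis genes rose in 15 and fell in 0 of 32, with the same counts adjusted over the list alone (median 0.10, adjusted p = 9.47e-04; adjusted p = 0.447 with an estimated correlation), led by BIRC5, survivin (0.69, 101 ± 1.37 to 163 ± 2.44 CPM), and CENPA, the centromeric histone (0.60).

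Lists called lower included NRF2 targets, of which 3 of 28 rose and 12 fell, or 3 and 14 adjusted over the list alone (median -0.16, adjusted p = 0.0047; adjusted p = 0.447 with an estimated correlation). ABCC3 (-1.19) fell most, and ME1, malic enzyme (0.94), rose. AKR1C1 rose by 0.30 but shares reads with close copies and was lost on log2 of the score plus 1 (adjusted p = 0.0645). Type I interferon response genes rose in 2 and fell in 9 of 30, with the same counts adjusted over the list alone (median -0.34, adjusted p = 0.0109; adjusted p = 0.353 with an estimated correlation). The call was lost among genes without a scan motif (adjusted p = 0.113), with 18 members, a median of -0.34 and a mean of -0.18 (SE 0.115) against -0.23 (SE 0.078) in all 30. IRF1 (-0.66) and IFIT2 (-0.65) fell and IFIT5 rose (0.21), and HERC5 (1.44) averaged under 1 CPM in both groups. Its call was lost without siNC replicate 1 or 2, without siCCNL2 replicate 1 and on log2 of the score plus 1 (adjusted p 0.0526 to 0.171). Hypoxia and glycolysis genes rose in 3 and fell in 10 of 32, with the same counts adjusted over the list alone (median -0.06, adjusted p = 0.0194; adjusted p = 0.57 with an estimated correlation). NDRG1 (-1.16) and the glucose transporter gene SLC2A3 (-0.78) fell, the glycolytic enzyme genes PFKL (0.56) and HK2 (0.27) rose. The list was lost without siCCNL2 replicate 1 (median -0.03, adjusted p = 0.0587) and after removal of the GC and length trend (0.101), which took the mean from -0.11 (SE 0.058) to -0.09 (SE 0.059). Cholesterol synthesis genes rose in 4 and fell in 11 of 24, or 6 and 12 adjusted over the list alone (median -0.15, adjusted p = 0.0314; adjusted p = 0.447 with an estimated correlation). MSMO1 (-0.50) was among those that fell and PMVK (0.69) among those that rose. The list was lost without siNC replicate 3 (adjusted p = 0.0515), without siCCNL2 replicate 1 (0.15) and after removal of the GC and length trend (0.101), which took the mean from -0.09 (SE 0.060) to -0.07 (SE 0.064).

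**Figure D3:**
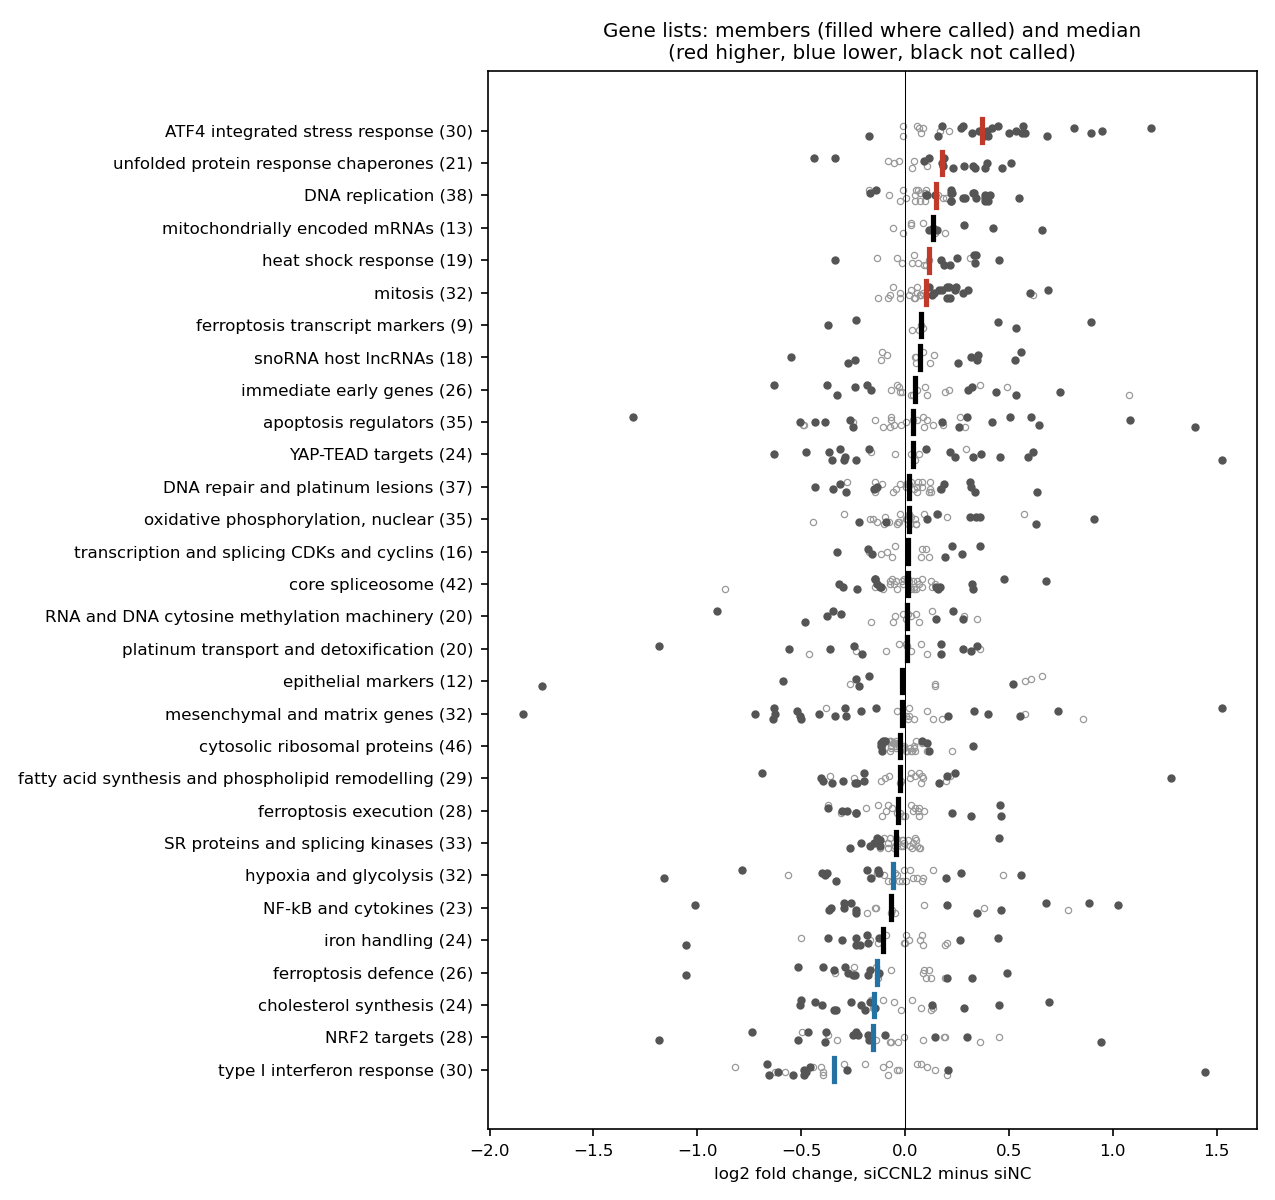
Log2 fold change of siCCNL2 minus siNC (x axis) for the tested members of each of 30 lists (y axis, number of members in brackets), filled where the gene was called, with the list median as a bar, red where camera called the list higher, blue where lower and black where not called. The ATF4 list has the highest median (0.37) and the type I interferon list the lowest (-0.34).

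The remaining lists described here were not called, and most had members moving both ways. Mesenchymal and matrix genes rose in 6 and fell in 14 of 32 (adjusted p = 0.0606), with COL6A3 (1.52) and LOX (0.74) higher and MMP2 and ITGB3 (-0.72) lower, and were called lower without siNC replicate 2, siCCNL2 replicate 2 or siCCNL2 replicate 3 (adjusted p 0.0363 to 0.0472), without a count filter (3.51e-04) and by fry (0.0051). They were also called lower among the 20 members without a scan motif (0.0139), where the median was -0.09 against -0.02 in all 32. Mitochondrially encoded transcripts rose in 6 and fell in 0 of 13 (adjusted p = 0.104), and were called higher without siNC replicate 1, siCCNL2 replicate 1 or siCCNL2 replicate 3 (adjusted p 4.02e-04 to 0.0446) and with the replicate number as a block (0.0101). These calls use the preset correlation (adjusted p = 0.859 with an estimated correlation, 0.442 by fry), and without siCCNL2 replicate 2 the median was 0.04 against 0.13 (0.747). Epithelial markers rose in 1 and fell in 5 of 12 (adjusted p = 0.184) and were called lower by fry (0.0051). Apoptosis regulators rose in 9 and fell in 6 of 35 (0.636), and DNA repair and platinum lesion genes rose in 6 and fell in 6 of 37 (0.921). Platinum transport and detoxification genes rose in 5 and fell in 5 of 20 (adjusted p = 0.921), with MGST1 (0.34) and LRRC8A, a subunit of an anion channel linked to platinum uptake (0.32), higher and the exporter gene ABCC3 and SLC31A1, a copper transporter linked to cisplatin uptake (-0.56), lower. Lists of the splicing apparatus gave no call: SR proteins and splicing kinases rose in 1 and fell in 8 of 33 (adjusted p = 0.216, called lower without a count filter at 0.0124), the core spliceosome rose in 7 and fell in 8 of 42 (0.921), and transcription and splicing CDKs and cyclins rose in 4 and fell in 3 of 16 (0.888). RNA and DNA cytosine methylation genes rose in 3 and fell in 5 of 20 (adjusted p = 0.707), with the demethylase genes TET1 (-0.91) and TET2 (-0.48) lower. Members of the YAP-TEAD (9 up, 9 down of 24), NF-kB and cytokine (6 and 8 of 23), immediate early (5 and 6 of 26), fatty acid and phospholipid (4 and 9 of 29), snoRNA host (6 and 3 of 18), nuclear oxidative phosphorylation (7 and 2 of 35) and ribosomal protein (4 and 6 of 46) lists moved in both directions, with adjusted p from 0.281 to 0.993. Cytosolic ribosomal proteins were called lower without siCCNL2 replicate 2 (adjusted p = 0.0015) and without a count filter (4.49e-06), where the fatty acid and phospholipid list was also called lower (0.04999). For ribosomal proteins the adjusted p was 0.958 with an estimated correlation and 0.683 by fry. In the NF-kB and cytokine list the median (-0.07) and the camera direction were negative, while the mean (0.05) and the fry direction were positive. Signs also differed between median, mean and test in the YAP-TEAD, platinum transport and cytosine methylation lists. Of the blood, endothelial and liver markers only 4 were counted high enough to test, which allowed no list test, and 3 of them fell, among them PECAM1 (-1.41) and CSF1R (-1.57). CSF1R ran from -2.50 to -0.79 over the alternatives and lost its call without siNC replicate 2 (adjusted p = 0.0601) or siCCNL2 replicate 3 (0.0509).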

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

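Of the alternatives described here, leaving out genes with a scan motif in the 3' UTR, removing the GC and length trend and testing KEGG pathways were chosen after the data were seen. CCNL2 was called lower under all 15 alternatives run on single genes (log2 fold change -0.49 to -0.41, adjusted p 5.86e-25 to 0.00101). The number of genes called, 5159, became 2584 among 7120 genes without a scan motif. Fewer genes were tested there, also because genes without a searched 3' UTR were left out. The called share was 36.3%, against 33.6% of all tested genes, which include those without a searched 3' UTR. Of the 12295 genes with a searched 3' UTR, 2413 were called higher and 2389 lower in the main fit. The comparison therefore does not show more calls among genes without a motif. The number called at least 2-fold, 359, became 130 on log2 of the TPM-like score plus 1, 1435 against a fold of 1.2, 1092 for a fold of at least 1.5 and 142 among genes without a scan motif. The counts against 1.2 and 1.5 follow from the lower fold required. Fewer genes were tested for the last, but rises were lost more than falls (45 higher and 97 lower, against 149 and 210). The share higher was 31.7%, against 41.5% of the 359. The motifs left out were picked on these fold changes, so this shift is not separate support for them. On log2 of the score plus 1, all 130 genes were among the 359. Adding 1 shrinks fold changes of genes with low scores by construction, but how much of the drop this makes up was not tested. The number of lists called, 10, became 0 by camera with an estimated correlation, which by construction also refers the statistic to the residual degrees of freedom of the libraries.

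Leaving out each library gave 4179 to 4768 genes called, 335 to 407 genes at least 2-fold, 130 to 134 of the 139 called named genes, 9 to 13 lists and a CCNL2 log2 fold change of -0.49 to -0.41. None of the 5159 calls reversed under any of the 15 alternatives. The DESeq2 Wald test called 4276 genes, all of them among the 5159. The median log2 fold change of all tested genes lay between -0.016 and 0.012 in these settings. Among named genes, 120 of 139 were called under every alternative. No called list reversed; the ATF4, unfolded protein response, NRF2, DNA replication and mitosis lists were lost only with an estimated correlation. Deviations from the group mean correlated at 0.043, 0.023 and 0.026 for equal replicate numbers and at -0.030 to 0.0048 for unequal ones. All were low, but the equal pairs were the highest, so a weak pairing is not excluded. With the number as a block 5234 genes and 11 lists were called. In data simulated at these depths with few genes changed, 66% of 1.5-fold changes were recovered. Recovery at other depths, or with as many changes as were called here, was not tested.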

Other observations

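The tests of KEGG pathways and of 3' UTR 7-mers were chosen after the results were seen. The splits were set before their values were seen, as were the tests of the ATF4 list, though these were chosen after the list result and the motif scan. Of 317 pathways of 10 to 300 tested genes, 0 were called by camera, 40 had an unadjusted p under 0.05, and 0 were called with an estimated correlation (9 unadjusted). The lowest adjusted p, 0.0864, was shared by cytokine and cytokine receptor genes (16 rose and 39 fell of 105, median log2 fold change -0.20), genes of haematopoietic lineages (6 and 15 of 32) and the malaria pathway (2 and 13 of 23). The pathway named ferroptosis had 5 higher and 7 lower of 33 (adjusted p = 0.825).

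The 6 libraries were also divided in other ways. The real split gave 5159 genes and 359 genes at least 2-fold, each reached by 1 of the 10 splits, itself, and the highest other value was 0 for both. It gave 10 lists, also reached by 1 of 10, and the highest other split gave 8 lists, with 1 to 7 in the remaining 8 splits. Every other split mixes libraries of both groups, so the group difference entered its spread and made calls of single genes unlikely. The 0 genes there therefore do not measure how often chance gives as many calls, and the 10 splits are too few for a share under 0.05. Camera with the preset correlation called lists in every split, also where 0 genes were called. The number of lists thus sets the real split apart far less than the number of genes does. Because the other splits keep part of the group difference, their list calls do not measure chance either.

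The siRNA sequences were not given in the sources used here. Bases 2 to 8, UCUCCGA, of 1 strand of a widely used control duplex are known as background. Whether this duplex was used, and whether that strand acts as a guide, is not known here. The 3' UTR match of these bases, TCGGAGA, ranked 2 of 16096 7-mers over 9970 genes by association with higher values in siCCNL2 (z 7.29). It came behind TGGAGAA (z 8.63), which pairs through G:U at position 7 of that strand. All 10 highest 7-mers held GGAGA, among them AGGAGAA (rank 3, z 6.84), which cannot pair at position 7. The rank of TGGAGAA therefore need not come from G:U pairing. Genes with the 8-base match averaged a log2 fold change of 0.27 (SE 0.065, 61 genes), those with 7 bases alone 0.12 (373), those with TGGAGAA alone 0.04 (2192) and those with none -0.01 (7344). Genes with a 7-base match in the coding sequence and none in the 3' UTR averaged 0.08 (SE 0.0081, 1446), a class that overlaps those with TGGAGAA alone and with none. Release from repression by the control siRNA, which would need that strand to act as a guide, is thus a candidate explanation for part of the rises. Fold changes were corrected for 3' UTR length and GC content before the scan, so only base composition beyond GC content could be tested. The averages by match class above were not corrected for either. Such composition is argued against for TCGGAGA, because the other 7-mers of the same bases had a median z of 0.107 (the next 4.68). TGGAGAA ranked 1 in each chromosome set when chosen on the other (permutation p = 1e-05, the smallest possible with 100000 resamples). Both sets come from the same libraries, so this rank does not bear on base composition. Of 2413 called higher genes with a searched 3' UTR, 1555 held none of these matches there. A match was held by 35.6% of called higher genes and by 22.5% of the other genes searched. Of the 13 named higher genes, 5 held a 7-base match and 6 TGGAGAA alone. Of the 17 named lower genes, 5 held either, among them LTBP2 with TCGGAGA and CGGAGAA, which fell all the same (log2 fold change -1.07). Named genes were picked by the size or p of the same fold changes that the scan used, so their matches are not separate support.

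Among lower values, CTGAGAT (z -5.84, rank 1) and the overlapping TCTGAGA (z -5.48) headed the scan, followed by TGGTGCT (z -5.36), which is not part of that sequence. Among 7-mers of its own bases the next z for TGGTGCT was -2.18. For CTGAGAT the next was the overlapping TCTGAGA itself, so these gaps cannot be compared. Averages by match class were again not corrected for 3' UTR length or GC content. Genes with the 8-base match averaged -0.057 (SE 0.016, 474 genes), those with 7 bases -0.01 (2403) and those with none 0.01 (7093). Genes with a 7-base match in the coding sequence and none in the 3' UTR averaged 0.003 (SE 0.0075, 1461), which is no fall. The motifs were picked on these genes and the sequence of the CCNL2 siRNA is not known here, so repression through its seed is left open. The other 7-mers of the same bases as CTGAGAT had a median z of -0.287, so 7-mers of this base composition were not low as a set. CTGAGAT was picked as the lowest of 16096 7-mers. Its gap to the others is therefore partly due to that choice and does not show what lowered its genes. The last coding exon of CCNL2 (exon 11 of 11 in CCNL2-201, chromosome 1, 1387466 to 1387473) holds TCTGAGA and CTGAGAT in overlap, but 2.45% of 9970 transcripts hold the 9-base span with CTCTGAG. TCTGAGA, the lowest 7-mer of the even autosomes and X, ranked 94 of 16090 in the odd autosomes (permutation p = 0.0214), but the lowest of the odd autosomes was ATGGTGC, which does not match it.

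The 25 members of the ATF4 list without TCGGAGA, CGGAGAA or TGGAGAA in the 3' UTR averaged 0.40 (SE 0.067) against 0.38 for all 30 (camera adjusted p = 1.78e-08), which argues against such matches as the whole cause. Both camera values of this paragraph use the preset correlation, and with an estimated correlation the call on the whole list was lost (adjusted p = 0.353). After removal of a trend over GC content and transcript length the mean was 0.40 (SE 0.058, camera adjusted p = 1.06e-08), which argues against that bias, though the trend explained little (R2 0.012). No library here held another CCNL2 siRNA or restored CCNL2, so loss of CCNL2, off-target effects of its siRNA and an indirect response to the control siRNA remain open and untested for this list.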
